A study of Phaseolus vulgaris with 18 samples.

How the data were processed

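RNA was measured in the pod wall of 2 common bean (Phaseolus vulgaris) lines grown in a climate chamber. A18-1, called the golden line here, has pods that turn from green to gold as they mature, and Renaya, called the green line, keeps green pods until ripening. The design text names pod walls sampled at 10, 14 and 18 days after flowering (DAF), which gives 6 groups of 3 libraries, and it calls the replicates independent biological repeats. One label field of the same libraries gives leaf as the tissue, and the extraction text mentions an adipose type. The design text is followed here, and the tissue field was not resolved. Per the labels' protocols, total RNA with an integrity number above 7.0 was enriched for poly(A) RNA, fragmented, reverse-transcribed and sequenced as read pairs on an Illumina NovaSeq instrument.

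The authors deposited estimated counts and FPKM values per gene for every library in 1 table, per the file headers. The estimated counts were whole numbers already, so rounding them changed nothing. At counts of a few reads the FPKM per count fell below each gene's usual ratio, which points to counts derived from coverage. FPKM, fragments per kilobase of transcript scaled to the mapped fragments of a library, were scaled by the authors, and no scaling between libraries beyond the total was stated. The aligner, counting program, versions and genome build are not given in the sources used here. Of the 25124 genes in the table, 17191 had assembled identifiers and no coordinates and 7933 had coordinates, and none of the genes named in the text had coordinates. 635 genes carried no gene name, and these held 2.20% to 3.97% of each library's counts. Gene descriptions in the table are names of the best-matching Arabidopsis proteins and were used as given. A reference table of gene symbols matched no identifier and was not used. Strand was not stated, so reads of overlapping and antisense genes could not be told apart, and reads of near-identical copies may have been split between them.

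The precision of a comparison was set by the spread between replicates more than by counting. The common dispersion was 0.154 with 12 residual degrees of freedom. No pair of replicates was a repeated library: the smallest chi-square between replicates, over genes with at least 20 counts in the pair, was 51.4 per gene. Floors below cover counting error only, and reads without molecular identifiers are not independent molecules.

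Gene counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by edgeR's expression filter, which left 22805 and dropped 2319, libraries were scaled by TMM, and 1 quasi-likelihood model of all 18 libraries with 1 mean per group was fitted. A two-sided quasi-likelihood test was run for each comparison, and p-values were adjusted by the Benjamini-Hochberg method over the tested genes. A gene was called changed at an adjusted p under 0.05 with no minimum fold. The plan named limma on log2(FPKM + 1) for a table of FPKM alone and edgeR for counts, so limma became an alternative. The comparisons were golden against green at each age, each pair of ages within a line, and the line by time interaction, which is the golden line's change from 10 to 18 DAF minus the green line's. Fold changes are given as log2 with their standard error (SE), and group levels as mean FPKM ± SD of 3 libraries. A fold against a group in which every library was at 0 is a lower bound, set against a floor of 3 counts over the group's 3 libraries.

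Lists of genes were fixed by patterns in the descriptions before the data were examined, as were the comparisons, the tests and the rule for named genes. The 20 lists were chlorophyll synthesis, chlorophyll breakdown, photosystem and antenna proteins, carbon fixation, plastid ribosome, carotenoid metabolism, flavonoid synthesis, pectin, wall loosening, cellulose and xylan, lignin and phenylpropanoid, ethylene, abscisic acid, auxin, NAC and WRKY factors, starch and sucrose, cell division, heat shock, defence, and seed storage and late embryo genes as a marker of seed tissue. Each list with at least 5 tested members was tested in the line comparisons, 18 against 10 DAF and the interaction with camera in limma 3.58.1, on log2 CPM (counts scaled to the effective library size) with a prior count of 2 and a preset inter-gene correlation of 0.01, and adjusted over the lists of that comparison. The plastid ribosome list had 3 members and no such test. 45 pairs of list and comparison passed, and 0 passed when the correlation was estimated from the residuals, so camera calls below rest on the preset value. Each list is also given as the number of members called over all genes and as the number called when p-values were adjusted over the list alone. Terms of the table's GO and KEGG annotation with 10 to 500 tested genes were tested for enrichment in genes called higher or lower. A one-sided Fisher's exact test was run against the annotated tested genes, 20264 for GO and 11399 for KEGG. It takes genes as independent, so its p do not measure replication.

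For the line comparisons and the interaction, the rule for named genes took from each list up to 3 called genes with the largest change and a mean FPKM of at least 5 in the higher group. It also took up to 5 described genes per direction with the largest change, a mean FPKM of at least 10 in the higher group and no overlap between groups. Genes described as pectin acetylesterase, STAY-GREEN, protochlorophyllide reductase, glutamyl-tRNA reductase, phytoene synthase or Golden2-like, and the locus Phvul.002G006200, were named whatever their value. 0 tested genes carried a STAY-GREEN or Golden2-like description, and those families are not analysed here. The text uses fewer genes than the rule allows and keeps its order. The circadian clock genes in the report were chosen after their values were seen.

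The procedure was tested on simulated counts in which 200 genes were changed. In simulations of golden against green at 18 DAF, edgeR recovered 16% of genes changed 2-fold, 62% changed 4-fold and 72% changed 8-fold. It made 5 false calls among 22517 genes (6.25% of its calls). In simulations of the interaction the shares were 2%, 44% and 64%, with 4 false calls.

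Alternatives to the choices above were limma on log2(FPKM + 1) with and without its trend, a pseudocount of 0.1, DESeq2 1.42.0, median-ratio size factors, quantile normalization, no filter, a filter of at least 5 FPKM in 3 libraries, the replicate number as a block, a fit of only the compared libraries, a minimum change of 2-fold, and each library left out in turn. Limma with its trend, DESeq2, the omission of genes without a name and 2 narrower lists were added after the data were seen.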

Results

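RNA was measured in pod walls of golden line A18-1 and green line Renaya at 10, 14 and 18 DAF, with 3 libraries per group. Total counts ran from 48757139 in the green line at 10 DAF (replicate 3) to 74377200 in the golden line at 14 DAF (replicate 2). Pearson correlations of log2 CPM across genes between replicates ran from 0.914, between replicates 1 and 2 of the golden line at 18 DAF, to 0.976. The 10 most abundant genes took 3.88% to 9.60% of the counts of a library. In a principal component analysis the first component held 40.7% of the variance and the second 18.1%. All 9 golden libraries lay between -134.1 and -37.3 on the first component. Green libraries lay between 142.2 and 159.2 at 10 DAF and between 4.62 and 25.0 at 18 DAF.

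**Figure D1:**
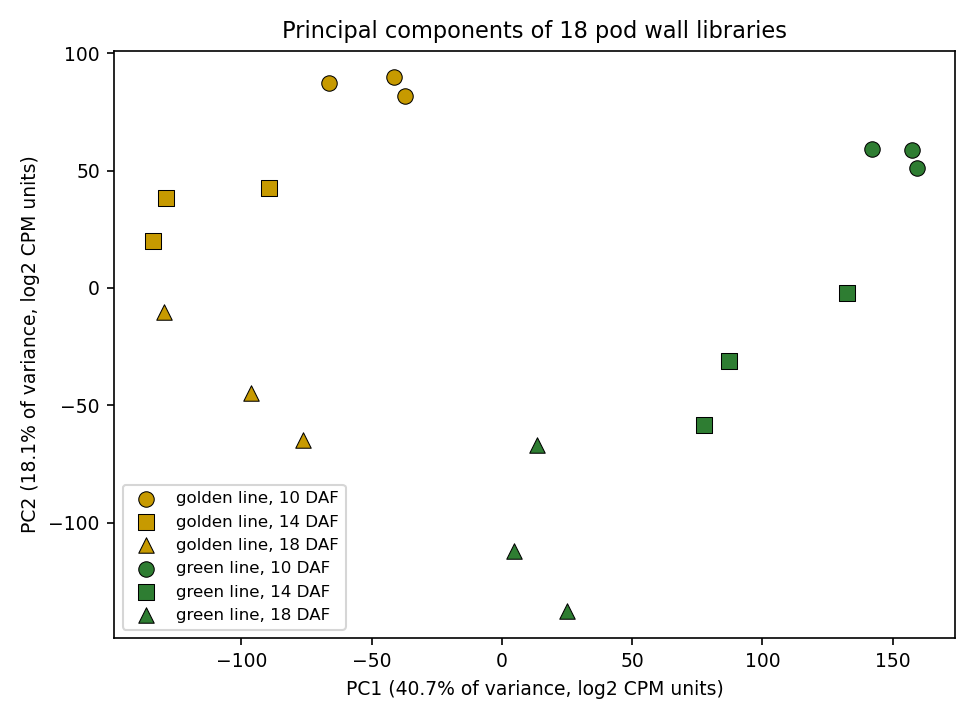
Principal component 1 (horizontal axis, 40.7% of variance) against component 2 (vertical axis, 18.1%) of log2 CPM, with 1 point per library, coloured by line and shaped by age. Golden libraries lie below -37 on component 1 at every age, and green libraries move from above 142 at 10 DAF to below 25 at 18 DAF.

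The comparison of the lines at 10 DAF asks how the pods differ while both are young and green. The antenna protein gene Phvul.001G242100, which encodes a light-harvesting protein of photosystem II, was 34.1-fold higher in the golden line (log2 fold change 5.09, SE 1.30, adjusted p = 0.0083), at 178 ± 46.4 FPKM against 5.24 ± 0.881. Phvul.007G252700, the H subunit of magnesium chelatase that commits porphyrin to chlorophyll, stood at 51.6 ± 16.3 FPKM against 9.89 ± 0.296 (log2 2.39, SE 0.54, adjusted p = 0.0040). Phvul.008G194300 (phytoene desaturation 1, an enzyme on the way to tocopherol and to the quinone needed for carotenoid synthesis) was 9.79-fold higher. In the opposite direction, Phvul.001G039700, a cytosolic small heat shock protein that binds unfolding proteins, stood at 2.88 ± 0.242 FPKM in the golden line and 312 ± 73.5 in the green line (log2 -6.73, SE 1.16, adjusted p = 6.8e-04). Cell division genes were also lower in the golden line, with 33 of 77 members lower and 4 higher.

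In all, 7443 of 22805 genes differed at 10 DAF, 3901 higher in the golden line and 3542 lower, and 4428 of them by at least 2-fold. Without golden replicate 3 the number was 4767. Photosystem and antenna genes were higher as a list, with 27 of 97 members called higher and 0 lower, and 24 when adjusted over the list alone (median log2 0.61, camera adjusted p = 7.0e-04, adjusted p = 0.81 with an estimated correlation). Phvul.009G258500, the P subunit of photosystem I, was 9.41-fold higher. Carotenoid metabolism had 9 of 20 members higher and 0 lower, and 11 higher when adjusted over the list alone (median 0.52, camera adjusted p = 0.0045, adjusted p = 0.81 with an estimated correlation). Chlorophyll synthesis had 4 of 15 members higher and 2 lower, the same counts when adjusted over the list alone, and its median of -0.04 differed in sign from its mean of 0.15 (camera adjusted p = 0.86). Among its members, hydroxymethylbilane synthase (Phvul.011G177100) was higher, at 28.4 ± 2.94 against 15.1 ± 0.444 FPKM, and uroporphyrinogen decarboxylase (Phvul.005G065500) was lower, at 19.1 ± 1.62 against 36.2 ± 2.73. Both enzymes act early in the shared porphyrin pathway. Glutamyl-tRNA reductase (Phvul.008G185100), the enzyme that controls entry into that pathway, was at 93.6 ± 5.10 against 58.3 ± 3.43 FPKM (log2 0.69, SE 0.25, adjusted p = 0.047). That call ended on omission of any of the 6 libraries, with adjusted p from 0.071 to 0.137.

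Chlorophyll breakdown had 2 of 8 members higher and 0 lower at 10 DAF, also when adjusted over the list alone (median 0.41, camera adjusted p = 0.20). Chlorophyllase 2 (Phvul.007G278100), which removes the phytol chain from chlorophyll, was 4.96-fold higher (log2 2.31, SE 0.30, adjusted p = 8.9e-05). Pheophytinase (Phvul.011G013400), which removes phytol from pheophytin, was at 12.1 ± 2.97 against 2.03 ± 0.169 FPKM (adjusted p = 0.024), and omission of any library but golden replicate 2 raised its adjusted p to between 0.053 and 0.078. Carbon fixation had 3 of 12 members higher and 0 lower (1 higher when adjusted over the list alone, camera adjusted p = 0.37). The plastid ribosome list had 1 of 3 members lower, also when adjusted over the list alone.

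Starch and sucrose genes were higher as a list at 10 DAF, with 16 of 45 members higher and 4 lower, the same when adjusted over the list alone (median 0.42, camera adjusted p = 0.031, adjusted p = 0.79 with an estimated correlation). Phvul.011G044000, a subunit of the enzyme that makes ADP-glucose for starch, was at 50.5 ± 2.65 against 2.34 ± 0.194 FPKM, and starch branching enzyme 2.2 (Phvul.009G011000) was 5.18-fold higher. NAC and WRKY factors, transcription factor families with roles in senescence and stress, had 25 of 133 members higher and 2 lower, and 22 and 1 when adjusted over the list alone (median 0.38, camera adjusted p = 0.031, adjusted p = 0.81 with an estimated correlation). NAC47 (Phvul.001G100200) was 23.2-fold higher. Without golden replicate 3 both list tests gave an adjusted p of 0.055, within ranges over the alternatives of 0.022 to 0.79 for starch and 0.0060 to 0.81 for the factors. Defence genes had 110 of 420 members higher and 35 lower, and 114 and 35 when adjusted over the list alone (median 0.71, camera adjusted p = 0.0038, adjusted p = 0.79 with an estimated correlation). Under the filter of at least 5 FPKM that list's median was 0.30 with a camera adjusted p of 0.22, and that p ran from 0.0017 to 0.79 over the alternatives. Osmotin 34 (Phvul.002G286500), an antifungal protein, was at 33.6 ± 28.7 against 0.414 ± 0.120 FPKM, a dirigent-like gene (Phvul.010G063800) was 55.7-fold higher, and chitinase A (Phvul.011G167000) was lower, at 1.45 ± 1.61 against 36.5 ± 13.5 FPKM.

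The cell division list was lower at 10 DAF, with 35 members lower and 4 higher when adjusted over the list alone (median -1.02, camera adjusted p = 6.0e-05, adjusted p = 0.79 with an estimated correlation). Cyclin A1;1 (Phvul.009G128200) stood at 3.59 ± 0.576 against 20.7 ± 6.44 FPKM and the mitotic kinase CDKB2;2 (Phvul.001G000500) at 14.1 ± 4.51 against 76.4 ± 24.8. Without golden replicate 3 their adjusted p rose to 0.060 and 0.074, and without green replicate 3 that of CDKB2;2 rose to 0.052. Over the alternatives these p ran from 3.1e-04 to 0.060 and from 9.5e-04 to 0.074. Among the 3542 genes lower in the golden line, KEGG ribosome genes numbered 262 against 73.0 expected (adjusted p = 2.6e-95) and DNA replication genes 46 against 19.6 (adjusted p = 1.7e-07).

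Heat shock genes went both ways at 10 DAF, with 56 of 227 members lower and 37 higher, and 58 and 38 when adjusted over the list alone (median -0.02, camera adjusted p = 0.37). The list takes in DnaJ co-chaperones besides heat-induced proteins. HSP90.1 (Phvul.004G107700), a heat-inducible chaperone, was 31.4-fold lower in the golden line, and a DnaJ-domain gene (Phvul.003G004300) was at 5.94 ± 0.627 against 0.0319 ± 0.0553 FPKM. Clock genes that peak late in the day in other plants, chosen after their values were seen, differed in the same libraries. All 6 genes described as GIGANTEA, PRR5 or FKF1 were higher in the golden line at 10 DAF (median log2 2.90) and at 14 DAF (median 2.18), and 1 of 6 at 18 DAF (median 0.62). PRR5 (Phvul.009G045000) stood at 61.5 ± 15.8 FPKM in the golden line and 2.48 ± 0.568 in the green line at 10 DAF, and at 21.6 ± 6.06 and 14.7 ± 6.05 at 18 DAF. The KEGG set for the plant circadian rhythm held 57 of the genes higher in the golden line at 10 DAF against 35.3 expected (adjusted p = 0.0062). The labels give no time of day for the sampling.

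Genes of the cell wall went both ways at 10 DAF. Wall loosening had 8 of 44 members higher and 10 lower (10 and 12 when adjusted over the list alone, camera adjusted p = 0.48). Expansin 11 (Phvul.009G019000), of a family that loosens growing walls, was at 0.139 ± 0.121 against 33.0 ± 5.56 FPKM, and the xyloglucan-modifying enzyme XTH6 (Phvul.003G231900) at 79.3 ± 44.0 against 2.33 ± 1.11. Cellulose and xylan had 11 of 71 members higher and 12 lower, also when adjusted over the list alone (camera adjusted p = 0.80), and its median of 0.02 differed in sign from its mean of -0.54. The fasciclin-like arabinogalactan protein FLA12 (Phvul.011G075050), of a group tied to secondary walls, was at 0 in every golden library against 9.90 ± 0.596 FPKM, at least 578-fold lower. A cellulose synthase-like gene (Phvul.009G226000) was at 7.74 ± 2.50 against 0.0710 ± 0.123 FPKM. Pectin had 15 of 89 members higher and 14 lower, also when adjusted over the list alone (camera adjusted p = 0.66). Pectin acetylesterases, which remove acetyl groups from pectin, had 3 of 10 members higher and 1 lower. Auxin had 27 of 157 members higher and 10 lower (22 and 9 when adjusted over the list alone, camera adjusted p = 0.37), among them an auxin efflux carrier (Phvul.002G117700, 53.7-fold higher) and a SAUR gene (Phvul.011G174700, 29.7-fold higher).

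For the remaining lists no camera test passed at 10 DAF. Flavonoid synthesis had 6 of 28 members lower and 0 higher (3 lower when adjusted over the list alone, median -0.84, camera adjusted p = 0.23), and without green replicate 3 that p was 0.045 (median -1.16), within 0.045 to 0.92 over the alternatives. Lignin and phenylpropanoid had 1 of 26 members higher and 1 lower, ethylene 4 of 25 higher and 5 lower, and abscisic acid 1 of 12 higher and 1 lower. When adjusted over the list alone these counts were 1 and 1, 5 and 6, and 0 and 1. The lignin median was 0.09, or 0 with members at 0 counts placed at their bound, and the camera direction was down. The ethylene median of -0.13 and mean of 0.24 differed in sign. Seed storage and late embryo genes, the marker of seed tissue, had 14 of 108 members higher and 12 lower (12 and 9 when adjusted over the list alone, camera adjusted p = 0.48). The largest differences were in genes near 0 in 1 line, where gene absence or poor mapping was not tested at any age. SPX2 (Phvul.003G164900) was at least 1898-fold and a glycosyl hydrolase (Phvul.008G135400) at least 1113-fold higher in the golden line. A P450 of the 82C group (Phvul.004G021300) was at least 2028-fold and sulfotransferase 2A (Phvul.011G111600) at least 1725-fold lower. A Rossmann-fold gene (Phvul.007G102100), at 0 in the golden line, averaged 34.0 ± 57.7 FPKM in the green line because 1 library held 100.6.

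At 14 DAF, when the golden line's pods are between green and gold by the design, genes of photosynthesis were higher in the golden line as a group. Of 97 photosystem and antenna genes, 70 were higher and 0 lower, 75 when adjusted over the list alone (median log2 1.26, camera adjusted p = 7.8e-13, adjusted p = 0.46 with an estimated correlation). The antenna gene Phvul.001G242100 stood at 376 ± 122 against 11.4 ± 14.4 FPKM (log2 5.07, SE 1.29, adjusted p = 0.0063), and the small subunit of rubisco (Phvul.004G073400), the enzyme that fixes carbon dioxide, at 5761 ± 825 against 1172 ± 452 FPKM (log2 2.30, SE 0.63, adjusted p = 0.0098).

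In all, 9474 genes differed at 14 DAF, 4644 higher in the golden line and 4830 lower, and 5652 by at least 2-fold. Chlorophyll synthesis had 10 of 15 members higher and 0 lower, also when adjusted over the list alone (median 0.61, camera adjusted p = 0.0011, adjusted p = 0.44 with an estimated correlation). The H subunit of magnesium chelatase (Phvul.007G252700) was 7.34-fold higher, a second H subunit gene (Phvul.001G132200) 2.69-fold, hydroxymethylbilane synthase (Phvul.011G177100) 3.14-fold and glutamyl-tRNA reductase (Phvul.008G185100) 2.68-fold. Chlorophyll breakdown had 5 of 8 members higher and 0 lower, also when adjusted over the list alone (median 0.53, camera adjusted p = 0.022, adjusted p = 0.46 with an estimated correlation). Pheophytinase (Phvul.011G013400) was 8.89-fold higher, chlorophyllase 2 (Phvul.007G278100) 6.31-fold, and pheophorbide a oxygenase (Phvul.011G086700), which opens the chlorophyll ring, 2.11-fold. Carbon fixation had 7 of 12 members higher and 1 lower, also when adjusted over the list alone (median 1.61, camera adjusted p = 0.022, adjusted p = 0.46 with an estimated correlation). Phosphoribulokinase (Phvul.002G133100) was 5.41-fold higher. Rubisco activase (Phvul.001G234300) was at 545 ± 225 against 91.4 ± 57.8 FPKM (adjusted p = 0.017, but 0.053 without golden replicate 1 and 0.068 without green replicate 1, within 0.0010 to 0.068 over the alternatives). The plastid ribosome list had 1 of 3 members higher, also when adjusted over the list alone. The KEGG antenna set held 28 higher genes against 6.49 expected (adjusted p = 2.4e-14), and the GO term for thylakoid membrane 205 against 59.5 (adjusted p = 1.9e-73).

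Carotenoid metabolism had 13 of 20 members higher and 1 lower at 14 DAF, also when adjusted over the list alone (median 0.89, camera adjusted p = 2.4e-04, adjusted p = 0.46 with an estimated correlation). Zeaxanthin epoxidase (Phvul.003G243800), which turns zeaxanthin into violaxanthin, was at 135 ± 42.7 against 19.7 ± 6.73 FPKM. Phytoene synthase (Phvul.008G195800), the entry enzyme of the pathway, was 4.17-fold higher, and 2 of 3 phytoene synthase genes were higher. The 2 protochlorophyllide oxidoreductase genes, whose enzyme carries out the light-driven step of chlorophyll synthesis, passed the test at neither 10 nor 14 DAF. Phvul.011G148900 had log2 fold changes of -0.05 (SE 0.34, adjusted p = 0.93) and 0.11 (SE 0.34, adjusted p = 0.82).

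Wall loosening had 17 of 44 members lower and 3 higher at 14 DAF, and 19 and 4 when adjusted over the list alone (median -1.09, camera adjusted p = 0.020, adjusted p = 0.44 with an estimated correlation). Expansin A8 (Phvul.006G077200) was at 2.70 ± 1.55 against 69.0 ± 39.0 FPKM, expansin 11 (Phvul.009G019000) at 0.0961 ± 0.166 against 12.9 ± 10.3, and XTH32 (Phvul.007G148500) was 65.5-fold lower. Pectin had 24 of 89 members lower and 7 higher (22 and 7 when adjusted over the list alone, median -0.36, camera adjusted p = 0.061). That p passed in 5 of 16 alternatives, among them omission of golden replicate 3 (0.045), and ran from 0.023 to 0.55. Pectin methylesterase inhibitors Phvul.007G218500 and Phvul.009G224200, of a family that blocks removal of methyl groups from pectin, were 14.8-fold and 13.6-fold lower. Pectin acetylesterases had 2 of 10 members higher and 3 lower. Cellulose and xylan had 12 of 71 members higher and 17 lower, also when adjusted over the list alone (camera adjusted p = 0.48). Lignin and phenylpropanoid had 1 of 26 members lower, cinnamyl alcohol dehydrogenase 9 (Phvul.002G268500, 2.81-fold lower), also when adjusted over the list alone, and its median of 0.20 differed in sign from the camera direction.

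Cell division had 41 of 77 members lower and 2 higher at 14 DAF, and 48 and 2 when adjusted over the list alone (median -1.24, camera adjusted p = 2.1e-06, adjusted p = 0.44 with an estimated correlation). A kinesin (Phvul.011G141500), a motor protein of the spindle class, was 6.13-fold lower and histone H2A 11 (Phvul.001G155700) 4.96-fold lower. KEGG ribosome genes numbered 266 among the genes lower in the golden line against 96.9 expected (adjusted p = 2.9e-69), and proteasome genes 47 against 18.8 (adjusted p = 1.5e-09). Heat shock genes had 69 of 227 members lower and 34 higher (71 and 36 when adjusted over the list alone, median -0.23, camera adjusted p = 0.058), in the libraries in which the afternoon clock genes were higher. The list's p passed without golden replicate 1 (0.048), golden replicate 2 (0.031) or green replicate 1 (0.018), and ran from 0.018 to 0.46 over the alternatives. The small heat shock gene Phvul.001G039700 was 68.5-fold lower, HSP90.1 (Phvul.004G107700) was 37.2-fold lower and an HSP20-like gene (Phvul.002G231500) stood at 8.92 ± 7.53 against 361 ± 205 FPKM.

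NAC and WRKY factors had 41 of 133 members higher and 7 lower at 14 DAF, also when adjusted over the list alone (median 0.97, camera adjusted p = 1.9e-04, adjusted p = 0.46 with an estimated correlation). WRKY40 (Phvul.010G161100) was 40.3-fold higher, NAC90 (Phvul.011G095500) 38.8-fold, and a NAC47 gene (Phvul.004G077400), at 0 in the green line, at least 562-fold. Defence had 128 of 420 members higher and 43 lower, also when adjusted over the list alone (median 0.72, camera adjusted p = 1.9e-04, adjusted p = 0.44 with an estimated correlation). Under the filter of at least 5 FPKM its median was 0.39 with a camera adjusted p of 0.12, and that p ran from 4.6e-05 to 0.44 over the alternatives. A TIR-NBS-LRR resistance gene (Phvul.004G135100) was at least 1124-fold higher, an NB-ARC resistance gene (Phvul.002G129566) at least 514-fold and osmotin 34 (Phvul.002G286500) 235-fold. Ethylene had 9 of 25 members higher and 4 lower (10 and 4 when adjusted over the list alone, camera adjusted p = 0.13, 0.045 without golden replicate 3, and 0.045 to 0.64 over the alternatives). Starch and sucrose had 13 of 45 members higher and 2 lower, also when adjusted over the list alone (camera adjusted p = 0.061, but 0.0499 without golden replicate 3 and 0.047 without green replicate 3, within 0.031 to 0.46 over the alternatives), with Phvul.011G044000 10.4-fold higher. Abscisic acid had 3 of 12 members higher and 1 lower (2 and 1 when adjusted over the list alone), and flavonoid synthesis 3 of 28 higher and 6 lower (2 and 5 when adjusted over the list alone, median 0.59, but -0.03 without golden replicate 1, camera adjusted p = 0.77). Auxin had 30 of 157 members higher and 27 lower, also when adjusted over the list alone, with a median of 0.12 and a mean of -0.01. A GH3 gene (Phvul.011G113000), of a family that attaches amino acids to hormones, was 27.6-fold higher. Seed storage and late embryo genes had 11 of 108 members higher and 27 lower (11 and 26 when adjusted over the list alone, median -0.80, but 0.41 without the lipid-transfer and 2S albumin superfamily, camera adjusted p = 0.083). Among the largest differences, SPX2 (Phvul.003G164900) was at least 1695-fold higher, an oxidoreductase (Phvul.009G207800) at least 1495-fold and a malectin-domain receptor kinase (Phvul.008G027200) at least 1280-fold. Sulfotransferase 2A (Phvul.011G111600) was at least 1142-fold lower, an X8-domain gene (Phvul.001G268000) at least 892-fold and a haloacid dehalogenase-like hydrolase (Phvul.005G164600) at least 801-fold.

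**Figure D2:**
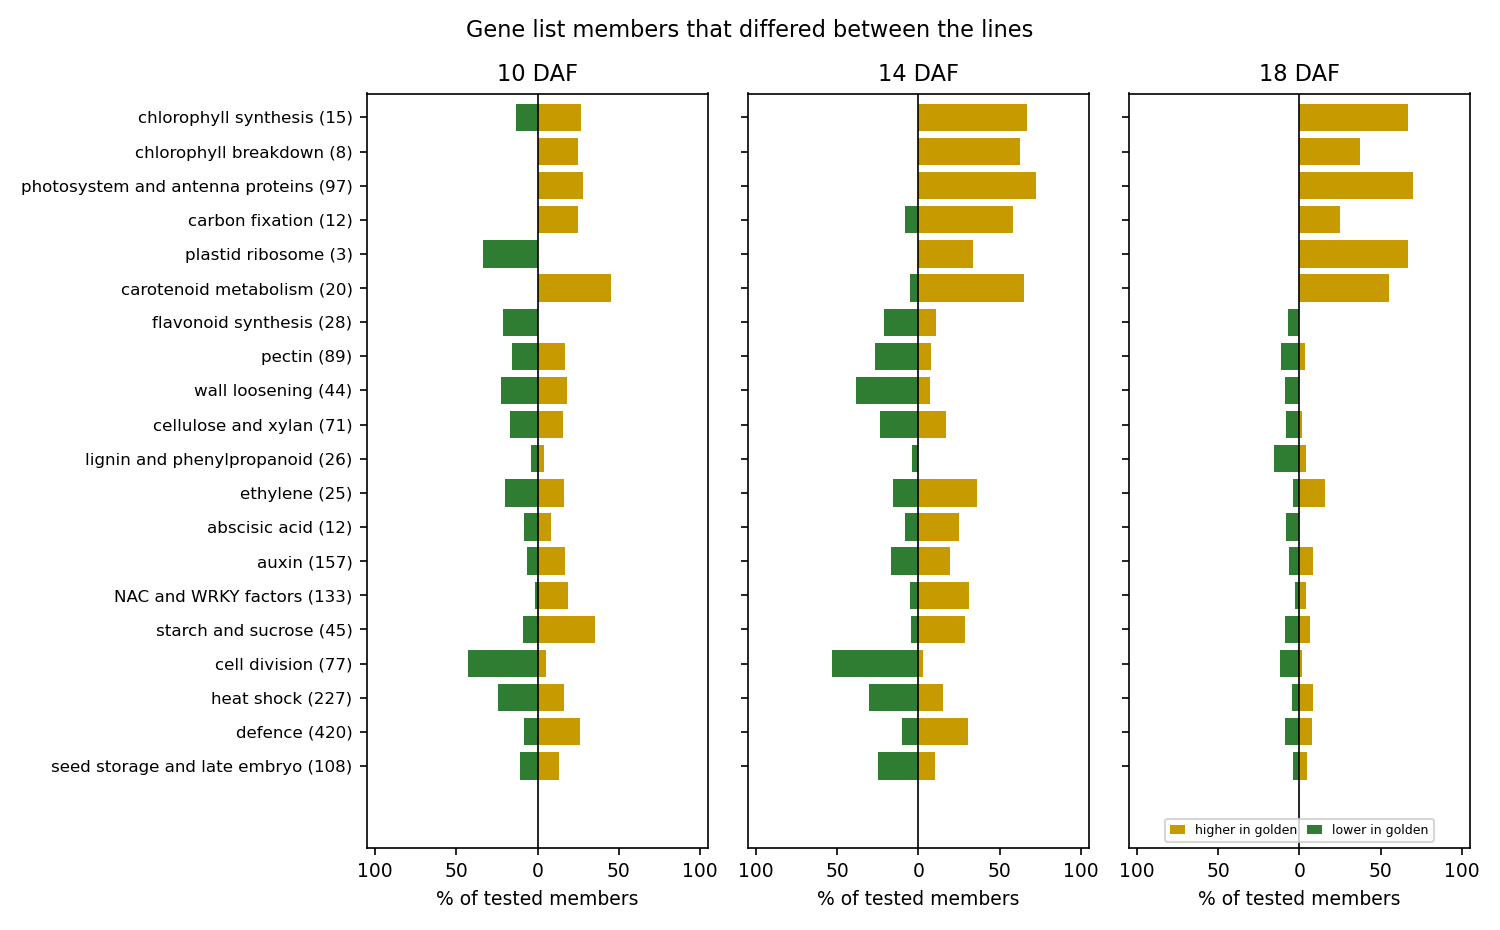
Percent of tested members of each gene list (horizontal axis, member numbers in brackets) called higher (gold bars, right) or lower (green bars, left) in the golden line, with 1 panel for each of 10, 14 and 18 DAF. Of 97 photosystem and antenna genes 27, 70 and 68 were higher, and of 77 cell division genes 33, 41 and 9 were lower.

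At 18 DAF, when the pods of the lines differ in colour by the design, genes that make chlorophyll and its binding proteins were higher in the golden line. Of 15 chlorophyll synthesis genes, 10 were higher and 0 lower, 12 when adjusted over the list alone (median log2 0.78, camera adjusted p = 1.2e-08, adjusted p = 0.17 with an estimated correlation). Both protochlorophyllide oxidoreductase genes were higher, Phvul.011G148900 at 121 ± 60.3 against 29.2 ± 5.34 FPKM (log2 2.16, SE 0.35, adjusted p = 0.0010) and Phvul.005G083700 at 589 ± 38.6 against 402 ± 56.3 FPKM. Glutamyl-tRNA reductase (Phvul.008G185100) stood at 98.0 ± 26.9 against 24.9 ± 9.20 FPKM (log2 2.13, SE 0.26, adjusted p = 1.1e-04) and the H subunit of magnesium chelatase (Phvul.007G252700) at 67.7 ± 39.4 against 9.28 ± 5.36. The call of Phvul.005G083700 (adjusted p = 0.024) ended without golden replicate 1 (0.058), golden replicate 2 (0.052), green replicate 2 (0.091) or green replicate 3 (0.071).

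In all, 3416 genes differed at 18 DAF, 1823 higher in the golden line and 1593 lower, and 2164 by at least 2-fold. A fit of the 6 libraries of this age alone called 628, and 12 of 29 called genes named for this age did not pass in it. Under limma on log2(FPKM + 1), which has no scaling between libraries beyond the total, the median of all genes shifted by -0.12 and 36.2% of the calls were higher, against 53.4% here. The photosystem median was 0.99 under that alternative. TMM factors of the golden libraries of this age were 0.909, 0.855 and 0.978. Photosystem and antenna genes had 68 of 97 members higher and 0 lower, and 75 when adjusted over the list alone (median 1.21, but 0.72 without golden replicate 2, camera adjusted p = 1.3e-21, adjusted p = 0.54 with an estimated correlation). The K subunit of photosystem I (Phvul.002G140800) stood at 171 ± 79.2 against 29.9 ± 12.4 FPKM. Chlorophyll-binding genes Phvul.007G062000 and Phvul.004G093200 were 15.8-fold and 6.46-fold higher, with adjusted p of 0.040 and 0.037. These p ran from 0.0019 to 0.13 and from 0.0025 to 0.19 over the alternatives. Both calls ended without golden replicate 2 (0.072 and 0.18), green replicate 1 (0.11 and 0.090) or green replicate 3 (0.13 and 0.10), and that of Phvul.007G062000 also without golden replicate 3 (0.072). The KEGG antenna set held 28 higher genes against 2.45 expected (adjusted p = 4.1e-26).

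Carbon fixation had 3 of 12 members higher and 0 lower at 18 DAF, also when adjusted over the list alone (median 1.36, camera adjusted p = 0.013, adjusted p = 0.57 with an estimated correlation). Its median was 0.17 without golden replicate 2 (camera adjusted p = 0.21) and 0.91 without green replicate 3 (0.056), with p from 9.6e-04 to 0.57 over the alternatives. A rubisco activase gene (Phvul.010G016000), whose product keeps rubisco active, was 9.30-fold higher. Chlorophyll breakdown had 3 of 8 members higher and 0 lower, and 4 when adjusted over the list alone (median 0.69, camera adjusted p = 0.013, adjusted p = 0.57 with an estimated correlation), and its median was 0.34 without golden replicate 2 (camera adjusted p = 0.18, within 9.6e-04 to 0.57 over the alternatives). Chlorophyllase 2 (Phvul.007G278100) was 3.27-fold higher. Carotenoid metabolism had 11 of 20 members higher and 0 lower, and 11 and 1 when adjusted over the list alone (median 0.74, but 0.41 without golden replicate 2, camera adjusted p = 3.5e-05, adjusted p = 0.54 with an estimated correlation). All 3 phytoene synthase genes were higher, Phvul.008G195800 3.69-fold, Phvul.006G024100 2.91-fold and Phvul.008G241500 1.97-fold (adjusted p = 0.013, but 0.058 without green replicate 3). Phytoene desaturation 1 (Phvul.008G194300) was 4.59-fold higher. The plastid ribosome list had 2 of 3 members higher, and 3 when adjusted over the list alone.

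**Figure D3:**
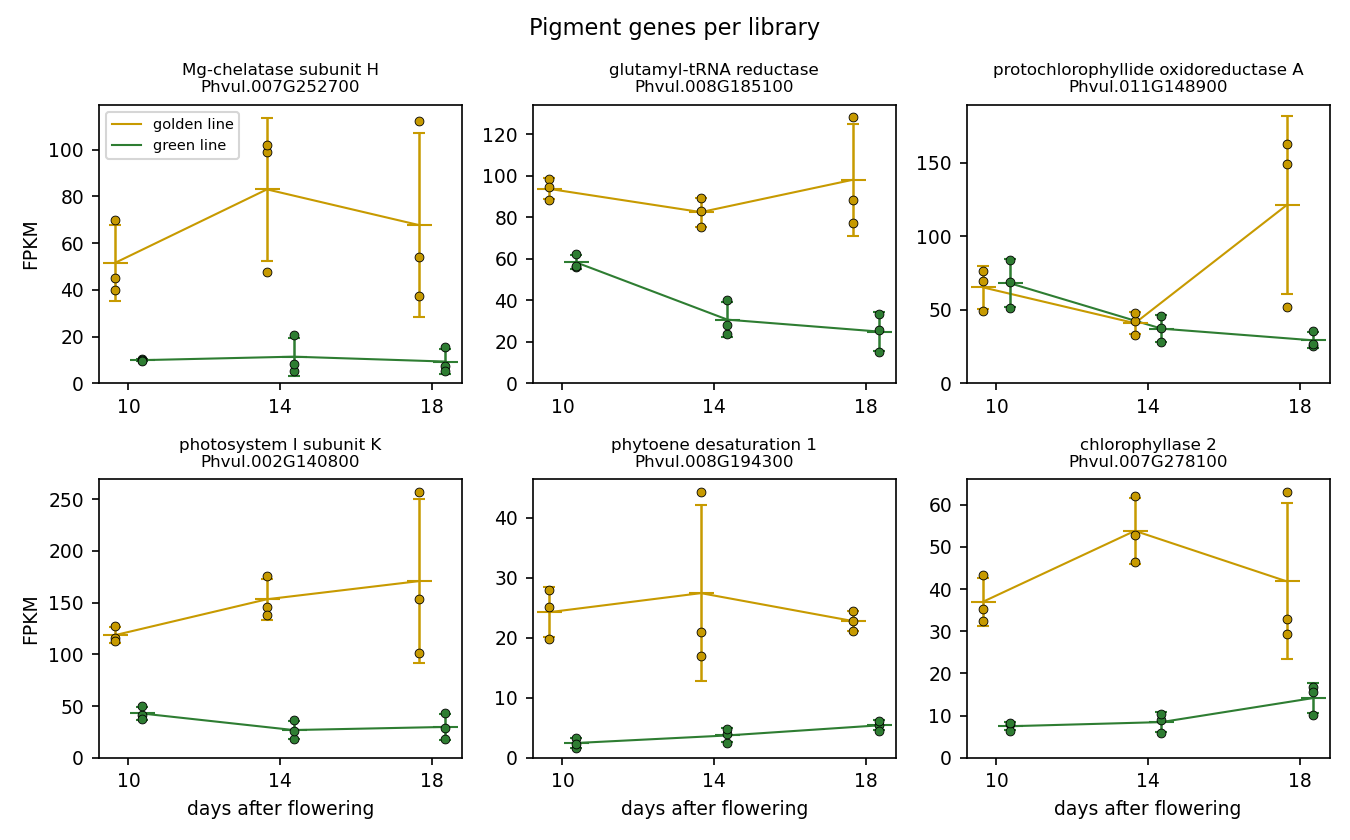
FPKM (vertical axis, from 0) against days after flowering (horizontal axis) for 6 pigment and photosystem genes in the golden and green lines, with points for libraries, horizontal marks joined by lines for means of 3 and bars for SD. Glutamyl-tRNA reductase stands at means of 93.6, 82.4 and 98.0 FPKM in the golden line and falls from 58.3 to 24.9 in the green line.

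Of the wall lists, cellulose and xylan passed at 18 DAF, with 6 of 71 members lower in the golden line and 1 higher, also when adjusted over the list alone (median -0.26, camera adjusted p = 0.039, adjusted p = 0.54 with an estimated correlation). The list's p was 0.079 without golden replicate 3 and 0.14 without green replicate 1 (median -0.11), 0.065 with limma and 0.0031 to 0.54 over the alternatives. FLA11 (Phvul.001G176400) stood at 12.3 ± 14.2 against 201 ± 70.0 FPKM and FLA12 (Phvul.011G075050) at 0.0138 ± 0.0239 against 7.85 ± 2.40. Laccase 17 (Phvul.008G119000), of a family that polymerises lignin, was 29.7-fold lower. Lignin and phenylpropanoid had 4 of 26 members lower and 1 higher, also when adjusted over the list alone (camera adjusted p = 0.81). The pectin methylesterase inhibitor Phvul.007G218500 was 34.6-fold lower (log2 -5.11, SE 0.39, adjusted p = 1.5e-06). Pectin had 10 of 89 members lower and 3 higher, also when adjusted over the list alone (camera adjusted p = 0.11, but 0.043 without golden replicate 1 and 0.025 without green replicate 3, within 0.025 to 0.84 over the alternatives), and 1 of 10 pectin acetylesterases was lower. Wall loosening had 4 of 44 members lower and 0 higher, also when adjusted over the list alone (median -0.49, or -0.41 with members at 0 counts at their bound). Its camera adjusted p was 0.080, but 0.039 without golden replicate 1 and 0.030 without green replicate 3, within 0.030 to 0.57 over the alternatives. The GO term for cell wall organization held 14 genes lower in the golden line against 3.81 expected (adjusted p = 0.0065).

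Cell division had 9 of 77 members lower and 1 higher at 18 DAF, also when adjusted over the list alone (median -0.14, camera adjusted p = 0.039, adjusted p = 0.84 with an estimated correlation). The list's median was 0.01 without golden replicate 2 (camera adjusted p = 0.68), and its p was 0.051 without golden replicate 3, 0.060 without green replicate 2 and 9.6e-04 to 0.84 over the alternatives. Heat shock had 19 of 227 members higher and 10 lower (18 and 10 when adjusted over the list alone, camera adjusted p = 0.39, but 0.030 without green replicate 3 and 0.030 to 0.92 over the alternatives). In that replicate the small heat shock gene Phvul.001G039700 stood at 448 FPKM, against 21.4 and 16.7 in the other green libraries of this age. Starch and sucrose had 3 of 45 members higher and 4 lower (3 and 5 when adjusted over the list alone, median 0.01, mean -0.12). Sucrose synthase 3 (Phvul.001G209600), which splits sucrose, was 3.73-fold lower, and starch synthase genes Phvul.009G052100 and Phvul.008G036600 were 2.64-fold and 2.42-fold higher. NAC and WRKY factors had 5 of 133 members higher and 4 lower (2 and 3 when adjusted over the list alone, median 0.03, mean -0.29), with NAC74 (Phvul.007G192100) 13.4-fold lower. Defence had 32 of 420 members higher and 36 lower (34 and 37 when adjusted over the list alone, camera adjusted p = 0.83). Osmotin 34 (Phvul.002G286500) was at least 1248-fold higher and an NB-ARC resistance gene (Phvul.002G129900) 139-fold lower. Flavonoid synthesis had 2 of 28 members lower, abscisic acid 1 of 12 lower and ethylene 4 of 25 higher and 1 lower. When adjusted over the list alone these were 1 lower, 1 lower, and 4 higher and 2 lower, and the ethylene median of 0.17 and mean of -0.04 differed in sign. Auxin had 13 of 157 members higher and 10 lower (12 and 10 when adjusted over the list alone, median 0.06, mean -0.08). Seed storage and late embryo genes had 5 of 108 members higher and 4 lower (4 and 1 when adjusted over the list alone), and the higher ones included lipid-transfer genes Phvul.003G219200 and Phvul.003G219100, at 437 ± 291 against 59.3 ± 11.1 and 444 ± 291 against 62.6 ± 12.2 FPKM. These neighbours had near-equal values, so reads may be split between copies. Among the largest differences were a P450 of the 72A group (Phvul.005G063900, at least 2896-fold higher), the glycosyl hydrolase Phvul.008G135400 (at least 1235-fold higher), the hydrolase Phvul.005G164600 (at least 1415-fold lower) and a RING/U-box gene (Phvul.011G118000, at least 976-fold lower).

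The line difference was shared by part of the genes across ages. 798 genes were higher in the golden line at all 3 ages, against 63.5 expected for independent lists, and 612 were lower, against 52.4. The 1410 shared genes were 56.6% higher, and 41.0% of 1545 were higher under limma on log2(FPKM + 1). Between 10 and 14 DAF 2465 genes were higher at both ages and 2605 lower at both, with 70 in opposite directions, and the correlation of fold changes across genes was 0.73. Between 10 and 18 DAF the numbers were 861, 680 and 195, with a correlation of 0.51, and between 14 and 18 DAF 1319, 945 and 108, with a correlation of 0.57. Genes are not independent replicates. 32 genes had under 0.1 FPKM in all 9 libraries of a line and at least 5 FPKM in all 9 of the other, 12 detected in the golden and 20 in the green line. Among them, the glycosyl hydrolase Phvul.008G135400 averaged 19.6 ± 1.13 FPKM over the golden libraries and 0 in every green library. The hydrolase Phvul.005G164600 averaged 22.2 ± 9.75 FPKM in the green line and 0 in every golden library.

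Phvul.002G006200 was named before the data were examined, from memory and as a pectin acetylesterase, as a possible candidate for the golden pod gene pv-ye. The table describes this locus instead as non-intrinsic ABC protein 6, so its link to pv-ye is uncertain. RNA levels were 18.3 ± 3.04 against 20.03 ± 0.971 FPKM at 10 DAF (log2 -0.13, SE 0.20, adjusted p = 0.67), 19.6 ± 2.42 against 13.7 ± 1.95 at 14 DAF (log2 0.49, SE 0.21, adjusted p = 0.070) and 12.5 ± 3.03 against 14.3 ± 3.33 at 18 DAF (log2 -0.05, SE 0.20, adjusted p = 0.90). At 14 DAF it passed the test with limma (adjusted p = 0.043), with DESeq2 and without green replicate 1 (log2 0.65, adjusted p = 0.040). It did not pass in 13 of its 18 alternatives. A change in its sequence was not analysed here.

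In the golden line, expansin A8 (Phvul.006G077200) fell from 101.5 ± 64.3 FPKM at 10 DAF to 0.713 ± 0.118 at 18 DAF (log2 -6.95, SE 1.05, adjusted p = 8.2e-04). WRKY75 (Phvul.001G088200), a factor tied to senescence and phosphate stress, rose from 1.18 ± 0.528 to 62.9 ± 33.9 FPKM (log2 5.89, SE 1.04, adjusted p = 0.0019). Ethylene genes rose as a list, with 10 of 25 members higher and 0 lower, 13 when adjusted over the list alone (median 0.96, camera adjusted p = 1.2e-04, adjusted p = 0.44 with an estimated correlation). Of 97 photosystem and antenna genes, 4 rose and 0 fell, 0 and 0 when adjusted over the list alone (median -0.02, mean 0.02, camera adjusted p = 0.93). Without golden 18 DAF replicate 2 that median was -0.50 with a camera adjusted p of 0.0021, within 0.0021 to 0.98 over the alternatives.

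In all, 4723 genes changed in the golden line from 10 to 18 DAF, 2587 up and 2136 down. The number was 2726 without replicate 1 of 10 DAF, 2789 without replicate 2 of 10 DAF and 2741 in a fit of these 6 libraries alone. 54.8% of the calls were up here and 28.2% under limma on log2(FPKM + 1), where the median of all genes shifted by -0.15. From 10 to 14 DAF 296 genes changed (157 up), and from 14 to 18 DAF 2426 (1297 up), but 144 and 44 in fits of the compared libraries alone. The first number was 9 to 73 without any 1 of the 3 libraries of 10 DAF or of replicates 1 and 2 of 14 DAF, and 1849 without replicate 3 of 14 DAF. The second was 651 without replicate 2 and 1253 without replicate 1 of 14 DAF, and 923, 4007 and 1446 without replicates 1, 2 and 3 of 18 DAF. Under limma 20.2% of the changes from 14 to 18 DAF were up, against 53.5%.

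In the golden line 6 lists passed as lower at 18 than at 10 DAF, some with few members called. Pectin had 23 of 89 members down and 8 up, and 27 and 8 when adjusted over the list alone (median -0.59, camera adjusted p = 1.2e-04, adjusted p = 0.44 with an estimated correlation). Cell division had 19 of 77 down and 3 up, and 23 and 7 when adjusted over the list alone (median -0.35, camera adjusted p = 0.0017, adjusted p = 0.53 with an estimated correlation). Wall loosening had 12 of 44 down and 5 up, and 14 and 6 when adjusted over the list alone (median -0.64, or -0.43 with members at 0 counts at their bound, camera adjusted p = 0.025, adjusted p = 0.44 with an estimated correlation). Expansin A1 (Phvul.008G037500) fell 9.90-fold and XTH9 (Phvul.005G111300) 11.1-fold. Lignin and phenylpropanoid had 3 of 26 down and 0 up, also when adjusted over the list alone (median -1.26, but -0.27 without replicate 3 of 10 DAF, camera adjusted p = 0.025, adjusted p = 0.53 with an estimated correlation), with cinnamyl alcohol dehydrogenase 9 (Phvul.001G004000) down 5.26-fold. Auxin had 18 of 157 down and 11 up, and 16 and 11 when adjusted over the list alone (median -0.47, but -0.09 under the filter of at least 5 FPKM, camera adjusted p = 0.025, adjusted p = 0.53 with an estimated correlation). Flavonoid synthesis had 4 of 28 down and 2 up, and 9 and 2 when adjusted over the list alone (median -1.55, camera adjusted p = 0.0079, adjusted p = 0.53 with an estimated correlation), with chalcone synthase gene Phvul.001G083000, at the entry to flavonoids, down from 162 ± 50.6 to 8.37 ± 5.91 FPKM. Without replicate 2 of 18 DAF the camera adjusted p was 0.11 for cell division, wall loosening and lignin and 0.088 for auxin. Without replicate 3 of 18 DAF it was 0.063 for wall loosening and 0.068 for lignin, and without replicate 3 of 10 DAF 0.11 for lignin. With limma it was 0.13 for flavonoid synthesis, wall loosening and lignin and 0.26 for auxin. The highest p over the alternatives, 0.44 for pectin and wall loosening and 0.53 for the other lists, came from the estimated correlation, and the lowest ran from 8.4e-06 for pectin and cell division to 0.019 for lignin.

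Heat shock genes rose in the golden line from 10 to 18 DAF, with 49 of 227 up and 15 down, and 60 and 18 when adjusted over the list alone (median 0.27, but 0.07 with limma, camera adjusted p = 0.0017, adjusted p = 0.44 with an estimated correlation). The small heat shock gene Phvul.001G039700 rose from 2.88 ± 0.242 to 86.4 ± 45.8 FPKM, the mitochondrial small heat shock gene Phvul.011G016100 from 25.7 ± 13.3 to 556 ± 283 and a DnaJ gene (Phvul.006G207700) 35.6-fold to 176 ± 127. Lycopene cyclase (Phvul.005G122400), which forms the ring ends of carotenes, rose from 2.73 ± 0.297 to 15.1 ± 4.86 FPKM. Basic chitinase Phvul.009G116700 rose 448-fold, and its near-identical neighbours may share its reads. Other large rises were a lectin receptor kinase (Phvul.004G158100), from 0 to 16.98 ± 9.64 FPKM, and a defensin-like gene (Phvul.005G071400), from 0.0921 ± 0.0935 to 81.7 ± 53.7. A dirigent gene (Phvul.005G032600) fell 156-fold, a GDSL lipase (Phvul.006G107300) 141-fold and NAC74 (Phvul.007G192100) 16.8-fold. Chlorophyll synthesis had 2 of 15 up and 0 down (1 up when adjusted over the list alone, camera adjusted p = 0.44), and carotenoid metabolism 4 of 20 up and 1 down, also when adjusted over the list alone (median 0.19, mean -0.04).

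In the green line, glutamyl-tRNA reductase (Phvul.008G185100) fell from 58.3 ± 3.43 FPKM at 10 DAF to 24.9 ± 9.20 at 18 DAF (log2 -1.18, SE 0.25, adjusted p = 0.0028) and hydroxymethylbilane synthase (Phvul.002G034500) from 107 ± 15.1 to 28.7 ± 6.77. Chlorophyll synthesis had 10 of 15 members down and 1 up, and 12 and 1 when adjusted over the list alone (median -0.79, camera adjusted p = 8.1e-04, adjusted p = 0.62 with an estimated correlation). Cyclin B2;3 genes, which drive mitosis, fell 17.7-fold (Phvul.002G115100) and 16.4-fold (Phvul.009G115900). WRKY75 (Phvul.001G088200) rose from 0.416 ± 0.0901 to 57.2 ± 57.6 FPKM (adjusted p = 3.5e-04).

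In all, 7960 genes changed in the green line from 10 to 18 DAF, 4395 up and 3565 down. 55.2% were up here and 45.1% under limma on log2(FPKM + 1). From 10 to 14 DAF 1887 genes changed (1160 up), and from 14 to 18 DAF 1586 (900 up), but 3317 and 91 in fits of these libraries alone. The first number was 403 and 751 without replicates 2 and 3 of 14 DAF and 707, 769 and 459 without replicates 1, 2 and 3 of 10 DAF. The second was 471 and 492 without replicates 1 and 3 of 14 DAF and 516 without replicate 1 of 18 DAF. The shares of changes that were up, 61.5% and 56.7%, were 44.9% and 41.8% under limma, and 46.3% with quantile normalization for 10 to 14 DAF.

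Photosystem and antenna genes had 20 of 97 down and 0 up in the green line, and 13 and 0 when adjusted over the list alone (median -0.46, camera adjusted p = 5.5e-05, adjusted p = 0.73 with an estimated correlation). Without green 18 DAF replicate 3 the median was -0.21 (camera adjusted p = 0.063, within 5.7e-07 to 0.73 over the alternatives). A PsbP-like gene (Phvul.008G015100), of a family at the oxygen-evolving side of photosystem II, fell 3.32-fold, and all 3 plastid ribosome genes fell, also when adjusted over the list alone. Cell division had 39 of 77 down and 10 up, and 42 and 10 when adjusted over the list alone (median -1.03, camera adjusted p = 2.0e-06, adjusted p = 0.62 with an estimated correlation). Flavonoid synthesis had 16 of 28 down and 1 up, and 19 and 2 when adjusted over the list alone (median -2.995, but -0.70 without replicate 2 of 10 DAF, camera adjusted p = 9.6e-04, adjusted p = 0.62 with an estimated correlation). Pectin had 21 of 89 down and 13 up, and 22 and 13 when adjusted over the list alone (median -0.46, camera adjusted p = 0.029, adjusted p = 0.62 with an estimated correlation). That p was 0.057 without replicate 2 of 10 DAF (median -0.29), 0.12 without replicate 3 of 18 DAF and 0.091 without the methylesterase inhibitors in the list, within 0.0077 to 0.62 over the alternatives. Polygalacturonase inhibitors Phvul.002G201600 and Phvul.002G201700, which block pectin-cutting enzymes, fell 22.8-fold and 19.6-fold. Expansin A8 (Phvul.006G077200) fell 44.6-fold.

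NAC and WRKY factors rose in the green line, with 34 of 133 up and 8 down, and 32 and 6 when adjusted over the list alone (median 0.69, camera adjusted p = 0.0069, adjusted p = 0.62 with an estimated correlation). Ethylene had 10 of 25 up and 1 down, also when adjusted over the list alone (median 0.83, camera adjusted p = 0.0035, adjusted p = 0.62 with an estimated correlation), with ERF13 (Phvul.010G050700) up 44.1-fold. Defence had 100 of 420 up and 27 down, and 92 and 25 when adjusted over the list alone (median 0.43, camera adjusted p = 0.0088, adjusted p = 0.62 with an estimated correlation). Under the filter of at least 5 FPKM that median was 0.20 (camera adjusted p = 0.71, within 0.0045 to 0.71 over the alternatives). The basic chitinase Phvul.009G116700 rose from 0.0468 ± 0.0456 to 60.6 ± 23.0 FPKM. Lycopene cyclase (Phvul.005G122400) rose 10.2-fold, laccase 17 (Phvul.008G119000) 70.0-fold, XTH6 (Phvul.003G231900) 56.1-fold and the ADP-glucose gene Phvul.011G044000 17.2-fold. Heat shock had 46 of 227 up and 22 down (43 and 22 when adjusted over the list alone, camera adjusted p = 0.67), with the DnaJ gene Phvul.006G207700 up 25.5-fold. In the same libraries 5 of the 6 afternoon clock genes rose (median 1.75). Cellulose and xylan had 20 of 71 up and 8 down (20 and 10 when adjusted over the list alone, camera adjusted p = 0.64). A PLATZ factor (Phvul.002G061300) rose from 0 to 17.9 ± 7.35 FPKM, a lipase gene (Phvul.006G107100) fell from 66.3 ± 9.26 to 0.0292 ± 0.0506, and a cellulose synthase-like gene (Phvul.005G001000) fell 892-fold.

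**Figure D4:**
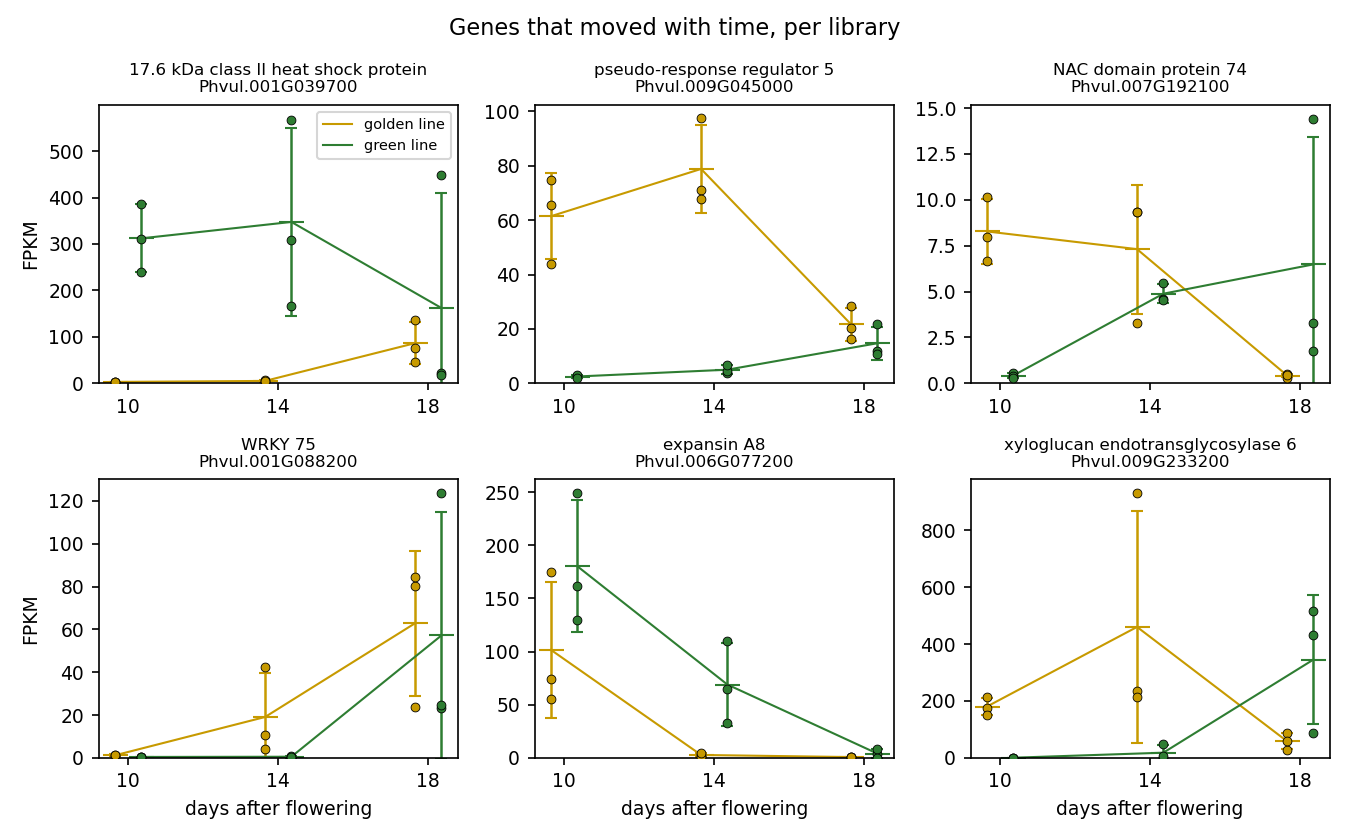
FPKM (vertical axis, from 0) against days after flowering (horizontal axis) for 6 genes in the golden and green lines, with points for libraries, horizontal marks joined by lines for means of 3 and bars for SD, not drawn below 0. The small heat shock gene stands at means of 2.88, 5.01 and 86.4 FPKM in the golden line and 312, 347 and 162 in the green line.

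The interaction asks which genes changed differently with age in the lines. Chlorophyll synthesis genes fell in the green line and did not fall with them in the golden line, with 7 of 15 members above 0 in the interaction and 0 below, 10 when adjusted over the list alone (median 0.95, camera adjusted p = 7.7e-06, adjusted p = 0.45 with an estimated correlation). Protochlorophyllide oxidoreductase Phvul.011G148900 went from 65.2 ± 14.4 to 121 ± 60.3 FPKM in the golden line and from 68.1 ± 16.3 to 29.2 ± 5.34 in the green line (log2 interaction 2.21, SE 0.48, adjusted p = 0.012). Glutamyl-tRNA reductase (Phvul.008G185100) had a log2 interaction of 1.43 (SE 0.35, adjusted p = 0.022, and 0.053 without golden 10 DAF replicate 2, the highest p of 24 alternatives). Both protochlorophyllide oxidoreductase genes and all 3 plastid ribosome genes had an interaction above 0. No wall list passed (camera adjusted p = 0.24 for cellulose and xylan, 0.64 for pectin and 0.76 for wall loosening), but the single gene XTH6 (Phvul.003G231900) went from 79.3 ± 44.0 to 31.7 ± 17.7 FPKM in the golden line and from 2.33 ± 1.11 to 128 ± 51.5 in the green line (adjusted p = 0.0012).

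In all, 2258 genes had an interaction, 860 above 0 and 1398 below. The number was 1397 and 1220 without golden replicates 2 and 3 of 10 DAF, 1378 and 1088 without green replicates 2 and 3 of 10 DAF and 1448 without green replicate 1 of 18 DAF. 38.1% of the interactions were above 0, and 48.3% with quantile normalization. With a pseudocount of 0.1 in limma the median of all genes shifted by -0.12. Photosystem and antenna genes had a median interaction of 0.56 (camera adjusted p = 5.2e-05, adjusted p = 0.91 with an estimated correlation), with 3 of 97 members above 0 and 0 below, 0 and 0 when adjusted over the list alone. It was 0.10 without golden 18 DAF replicate 2 (camera adjusted p = 0.21), 0.33 without green 18 DAF replicate 3 (0.079) and 0.28 with quantile normalization (0.070), with p from 5.6e-09 to 0.91 over the alternatives. The rubisco activase gene Phvul.010G016000 went from 11.4 ± 1.65 to 58.4 ± 30.8 FPKM in the golden line and from 27.4 ± 4.17 to 7.05 ± 2.83 in the green line. Defence had 30 of 420 members below 0 and 7 above, also when adjusted over the list alone (median -0.76, camera adjusted p = 3.5e-04, adjusted p = 0.73 with an estimated correlation). With quantile normalization its camera adjusted p was 0.071 and under the filter of at least 5 FPKM 0.14, within 1.2e-04 to 0.73 over the alternatives. NAC and WRKY factors had 12 of 133 below 0 and 1 above, also when adjusted over the list alone (median -0.55, camera adjusted p = 0.014, adjusted p = 0.84 with an estimated correlation). That p was 0.12 without golden 18 DAF replicate 2 and 0.061 without green 18 DAF replicate 2, within 0.0011 to 0.84 over the alternatives. NAC74 (Phvul.007G192100) went from 8.28 ± 1.77 to 0.422 ± 0.0979 FPKM in the golden line and from 0.417 ± 0.149 to 6.48 ± 6.93 in the green line (log2 -8.00, SE 0.94, adjusted p = 2.3e-04).

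Cell division had 9 of 77 members above 0 and 2 below, and 9 and 3 when adjusted over the list alone (median 0.57, camera adjusted p = 0.014, adjusted p = 0.84 with an estimated correlation), and its p was 0.10 without golden 18 DAF replicate 1, within 5.3e-05 to 0.84 over the alternatives. Heat shock had 26 of 227 above 0 and 13 below, and 35 and 19 when adjusted over the list alone (median 0.21, camera adjusted p = 0.047, adjusted p = 0.84 with an estimated correlation). Its p lay between 0.053 and 0.19 without any 1 of 8 of the 12 libraries, with all but golden 10 DAF replicate 2, green 10 DAF replicate 2 and green 18 DAF replicates 1 and 3 ending the call. It was 0.072 without a filter, 0.11 under the filter of at least 5 FPKM, 0.15 with quantile normalization and 0.089 with limma, and the list passed in 8 of 21 alternatives (0.0058 to 0.84). Starch and sucrose had 4 of 45 below 0 and 0 above, also when adjusted over the list alone (median -0.32, camera adjusted p = 0.043, adjusted p = 0.84 with an estimated correlation). Its p lay between 0.051 and 0.14 without golden replicate 3 of 10 DAF, golden replicates 1 or 3 of 18 DAF, green replicate 3 of 10 DAF or green replicate 2 of 18 DAF. It was 0.087 under the filter of at least 5 FPKM and 0.051 with quantile normalization, and the list passed in 13 of 21 alternatives (0.0050 to 0.84). Chlorophyll breakdown, carotenoid metabolism and flavonoid synthesis had 0 members called, also when adjusted over the list alone. Pectin had 10 of 89 below 0 and 5 above (12 and 7 when adjusted over the list alone, camera adjusted p = 0.64), among which 3 of 10 pectin acetylesterases were below 0. KEGG ribosome genes numbered 76 among the interactions above 0 against 18.2 expected (adjusted p = 1.6e-25), and genes of cutin, suberin and wax synthesis, which build the pod's surface layer, 16 among those below 0 against 3.80 (adjusted p = 7.1e-05).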

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

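Tests of a single library filed under the wrong line, of a lead in pod age for photosystem genes, and of time of day for photosystem genes and for the green line's change with age were chosen after the results were seen.

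The chlorophyll synthesis list and single heat shock and wall genes changed with age by different amounts in the lines, and 2258 genes passed the test of that difference, the line by time interaction (1088 without replicate 3 of the green line at 10 DAF). Among lists, none of which passed with an estimated correlation (adjusted p = 0.45 to 0.91), the median log2 interaction was 0.95 for chlorophyll synthesis, 0.56 for photosystem and antenna genes (0.10 without golden 18 DAF replicate 2), 0.57 for cell division, 0.21 for heat shock, -0.76 for defence, -0.55 for NAC and WRKY factors and -0.32 for starch and sucrose, of which heat shock passed in 8 and starch and sucrose in 13 of 21 alternatives. Genes whose change in the golden line lay above that in the green line were protochlorophyllide oxidoreductase (Phvul.011G148900, 2.21), glutamyl-tRNA reductase (Phvul.008G185100, 1.43), rubisco activase (Phvul.010G016000, 4.47), plastid ribosomal protein genes (Phvul.010G003200, 1.35, and Phvul.004G171400, 1.26), an ethylene-responsive factor (Phvul.007G217800, 4.13) and small heat shock genes (Phvul.001G039700, 5.94, and Phvul.011G016100, 4.88). Genes below 0 were a phosphoribulokinase-family gene (Phvul.003G180800, -1.67), the auxin efflux carrier Phvul.002G117700 (-6.74), a SAUR gene (Phvul.011G174700, -6.00), NAC74 genes (Phvul.007G192100, -8.00, and Phvul.001G161700, -4.88) and a DnaJ gene (Phvul.003G004300, -5.98). No wall list passed, and single wall genes below 0 were an expansin-like gene (Phvul.003G228000, -8.20), XTH6 (Phvul.003G231900, -6.93), a cellulose synthase-like gene (Phvul.009G226000, -6.95) and a xyloglucan endotransglycosylase (Phvul.009G233200, -11.29, from 180.2 to 58.0 FPKM in the golden line and from 0.378 to 345 in the green line). A beta-1,3-glucanase (Phvul.001G128500, -8.98) was also below 0, and its near-identical neighbour may share its reads. The fitted values of a GDSL lipase (Phvul.003G056700, -13.44) and a PLATZ factor (Phvul.002G061300, -9.79) involve a green group at 0 counts and are no bounds. The call of Phvul.003G228000 ended without replicate 3 of the golden line at 10 or 18 DAF or replicates 1 or 3 of the green line at 10 DAF, with adjusted p from 0.052 to 0.060 (from 2.1e-04 to 0.060 over its alternatives). The call of Phvul.002G061300 ended with limma (log2 -1.95) and with quantile normalization (log2 -1.69), and its adjusted p ranged from 9.8e-06 to 0.13.

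Most photosystem and antenna genes were higher in the golden line at 14 and 18 DAF. With quantile normalization or median-ratio size factors the lowest median at 14 and 18 DAF was 0.88, which argues against scaling between libraries. 0 of 18 libraries had under 90% of line-specific genes on their own side, which argues against 1 library filed under the wrong line, and an exchange of all labels of the lines was not tested, although higher photosystem RNA in the line whose pods turn gold runs against their colour. A more advanced age of the golden pods is argued against, less firmly, by the green line. There the 70 members higher in the golden line at 14 DAF changed by a median of -0.42 from 10 to 18 DAF. The whole list's -0.46 was -0.21 without green 18 DAF replicate 3. Time of day is too, by the list's median of 1.21 at 18 DAF, where the afternoon clock genes differed by a median of 0.62. Without golden replicate 2 the list's was 0.72, no longer within 1.5 times of the 1.26 at 14 DAF. A difference between the genotypes may remain and was not tested.

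The line difference at 10 and 14 DAF resembled the green line's change with age. The lower of 2 correlations across genes, on different libraries, was 0.311 (0.392 with quantile normalization). Median-ratio factors (0.312) shift genes alike and cannot test scaling. A lead of the golden line in pod age could give this pattern. So could time of day, since the afternoon clock genes rose by a median of 1.75 on the log2 scale from 10 to 18 DAF in the green line. The labels give no sampling hour, and the tests favour neither over the other.

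More heat shock genes were lower than higher in the golden line at 10 and 14 DAF. Without any 1 of the 12 libraries at least 45 members were lower (56 at 10 DAF and 69 at 14 DAF with all), which argues against a single library. The afternoon clock genes differed between the lines by a median of 2.90 on the log2 scale at 10 DAF, so a difference in the hour of sampling may lie behind part of the pattern. A difference between the genotypes in clock or heat response stays open and was not tested.

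Other splits of the libraries were counted for each comparison. With 3 libraries against 3 there are 10 splits, which cannot give a share under 0.05. The real split and the highest other called 7443 and 0 genes at 10 DAF, 9474 and 0 at 14 DAF and 3416 and 39 at 18 DAF. In the golden line they called 296 and 1 (14 against 10 DAF), 2426 and 565 (18 against 14 DAF) and 4723 and 0 (18 against 10 DAF), and in the green line 1887 and 2, 1586 and 0, and 7960 and 0. In each of these 1 of 10 splits, the real one, reached the real count. Other splits called 0 at 10 and 14 DAF, so the 1410 genes shared by all 3 ages add no test. There 1 of 100 drawn regroupings reached the real count (highest other 0). For the interaction 2 of 100 did, the real one and another that called 5554 genes, and others called 2004 and 1846. The regrouping with 5554 kept the 3 green libraries of 10 DAF together, and whether that gave its count was not tested.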

How the results depend on the processing

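Limma with its trend, DESeq2, the omission of genes without a name and the narrower pectin and seed lists, and the alternatives for the enrichment of terms, were tests chosen after the data were seen. No named gene that passed changed sign under any alternative, and of lists that passed, cell division at 18 DAF had a median of 0.01 without golden replicate 2 (-0.14 with it) and did not pass there. Where a cause is not stated below, the cause was not tested. A minimum change of 2-fold, which removes small changes by construction, left 4428, 5652 and 2164 genes between the lines at 10, 14 and 18 DAF, 849 shared by all ages, 1344 and 2781 in the golden line (18 against 14 and 18 against 10 DAF), and 1148 and 4779 in the green line (14 against 10 and 18 against 10 DAF). DESeq2 called 2067 and 4318 genes (golden 14 against 10 and 18 against 14 DAF), 3428 and 3446 (green, likewise) and 4039 (interaction), and on simulated 18 DAF counts it made 42 false calls and edgeR 5. A fit of only the compared libraries called 628 genes at 18 DAF, 144, 44 and 2741 in the golden line (14 against 10, 18 against 14 and 18 against 10 DAF) and 3317 and 91 in the green line (14 against 10 and 18 against 14 DAF). Pooled spread differed (chi-square per gene up to 729 in golden 18 DAF and 108 at 10 DAF). The golden line's 296 changes from 10 to 14 DAF became 627 with a pseudocount of 0.1, 483 with the stricter filter, 1252 with quantile normalization, 873 with limma without its trend and 899 with it. Replicate numbers do not pair the libraries, and with the replicate block this count was 53 and that of green 18 against 14 DAF was 1035. With each library left out in turn the counts ran from 4767 to 6062 (10 DAF), 7217 to 9336 (14 DAF), 2422 to 3643 (18 DAF), 9 to 1849, 651 to 4007 and 2726 to 5339 (golden 14 against 10, 18 against 14 and 18 against 10 DAF), 403 to 2305, 471 to 1504 and 5659 to 7244 (green, likewise), 1088 to 3317 (interaction) and 990 to 1705 (shared). The 4007 and the interaction's 3317 came without golden replicate 2 of 18 DAF. The number of list tests that passed, 45, was 0 with an estimated correlation, 38 to 45 under the other alternatives and 37 to 47 with a library left out. Genes listed near 0 in 1 line numbered 14 with a limit of 0.01 FPKM, 93 with at least 1 FPKM in the other line and 32 to 35 with a library left out. For single named genes 1957 comparisons with an alternative kept their side of the threshold, 26 lost it and 4 gained it, and with a library left out 1087 kept it, 33 lost it and 1 gained it. For list medians these numbers were 897, 80 and 11, and 686, 38 and 15, and beside these the median of a list that had not passed changed sign 50 and 59 times, and with a library left out a named gene that had not passed did so 7 times. Medians of passing lists that fell more than 1.5-fold without a change of call included wall loosening in golden 18 against 10 DAF, -0.18 without a filter (-0.64 with it). At 18 DAF the simulation recovered 0% of genes changed 1.5-fold. It changed 200 genes against 3416 called, so the shares missed or false in the data, whose groups differ in spread, are unknown.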

Other observations

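The tests in this part were planned, and the terms were picked after their values were seen. Terms enriched among genes higher in the golden line at 10 DAF included ADP binding, the term of nucleotide-binding resistance proteins (82 genes against 46.2 expected, adjusted p = 5.7e-05), and peroxisome genes (50 against 26.9, adjusted p = 8.0e-04). Genes lower in the golden line at 18 DAF were enriched for O-acetyltransferase activity (15 against 3.88, adjusted p = 0.0024). In the interaction, genes of the response to heat were enriched above 0 (25 against 5.73, adjusted p = 1.2e-07).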
